A study of Mus musculus with 2 samples.

How the data were processed

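Long-read RNA sequencing of the left cerebral cortex was analysed for 2 libraries, which form a single group. Per the labels, both came from male B6CASTF1/J mice, the F1 hybrid of a C57BL/6 and a CAST/Ei parent, at 2 months of age, each made from 2 µg of total RNA, and they are biological replicates 1 and 2 of the same experiment. The biosample labels name different mice, while the experiment text names a single mouse and both libraries carry the same donor record. Where the labels leave this open, a difference between these samples may be technical. The p-values of the main tests between the libraries allow for read sampling only, and none measures the spread between mice.

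Per the file headers, the deposited tables hold the authors' read counts per transcript model, in whole reads and not normalized, and each library has its own set of transcript models in the mm10 assembly with TALON named as their source and GENCODE M21 as the annotation. TALON is a tool that assigns each long read to an annotated transcript or gives it a model of its own. The authors' tables class each model as known, as an incomplete splice match (ISM, part of the splice chain of an annotated transcript), as NIC (annotated splice sites in an unannotated combination), as NNC (at least 1 unannotated splice site), or as genomic, antisense or intergenic, per the file headers. The sequencing platform, the aligner, the read filters and the versions of these tools are not given in the sources used here. Of the 141862 annotated transcripts in the models, 141862 were in the reference annotation. The models were not filtered on read number in the deposited tables, since 63.5% of the models in replicate 1 and 64.9% in replicate 2 had 1 read. The labels name ERCC and SIRV spike-ins, and the annotation held 96 ERCC sequences, whose reads were left out of library totals.

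Reads were summed per annotated gene and divided by all assigned reads without spike-ins to give CPM, reads per 1e6 assigned reads. The counting of strand is not given in the sources used here, so genes that overlap, genes with a near-identical copy and antisense models are uncertain. Models absent from the annotation carry numbers made separately for each library, so spliced models were matched by chromosome, strand and exact intron chain, and genes absent from the annotation were left out of the number of detected genes. Single-exon models outside the annotation were pooled into 1 structure per gene for the comparison of all structures, a choice made after seeing the data. The reason was that the class of overlapping single-exon models could differ between the libraries. A gene counted as detected with 5 reads in each library. Shares of transcripts were computed for genes with 50 known-transcript reads in each library. Exon inclusion was the number of reads whose model holds an annotated internal exon, over those plus the reads whose model has an intron spanning it, for exons with 20 such reads in each library. Exons at 10 to 90% in each library were called alternative, those over 95% in each near-constitutive, and those of 27 nt or shorter microexons. The allele of a read was not analysed here.

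With 1 group there was no contrast between conditions, and every test compared these 2 libraries or compared genes and exons within them. edgeR gave the TMM scaling and the common dispersion over genes with 10 reads in total. The split of each gene's reads between the libraries was tested against the scaled split by a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05. That test counts read sampling as the only source of spread. The share of the leading known transcript was compared by a two-sided Fisher's exact test with the same adjustment. Inclusion of microexons and longer exons was compared by a two-sided permutation test with 100000 resamples, and shares of exon lengths by two-sided Fisher's exact tests. Exons and genes are not independent replicates. Intervals for shares are 95% Wilson intervals, and the floor for a gene with no reads was 3 counts, 2.88 CPM in replicate 1 and 6.33 CPM in replicate 2. Reads carry no molecular identifiers in these tables and are not independent molecules if the cDNA was amplified, so intervals and floors cover counting error only.

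The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 15 genes with the highest mean CPM outside the mitochondrial genome, and of each list the 3 members with the highest mean CPM (2 for lists of other tissues) with the lowest member where it was under 1 CPM in each library. It also took, of the genes listed for alternative splicing in brain, each gene with 100 known-transcript reads in each library whose leading transcript held under 60% in each, and the alternative exon nearest to 50% inclusion in up to 15 genes. The 5 genes with the largest fold in each direction among those past the test with 100 reads, the 10 unannotated splice chains with the most reads in the weaker library, and up to 5 genes with a changed transcript share completed it. Some genes that the rule took were not used here. Of 32 fixed lists, 1 layer 6 symbol and 1 splicing symbol were not in the annotation. Positions of genes and exons are 1-based in mm10. Gene lengths and GC content were those of the leading transcript and covered 95.1% and 95.0% of tested genes.

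Alternatives changed the read minimum, the transcripts counted, the scaling (DESeq2 size factors or library totals), the treatment of spread (a negative binomial exact test in edgeR), the depth (the deeper library thinned) and the replicates used. A correction for transcript length and a run without striatal genes were chosen after seeing the data, as was the pooling of single-exon models named above.

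The statistical steps were tested on simulated data, and the tests of the length correction, of the list comparison and of exon lengths were added after seeing the data. Matching of splice chains, an exact comparison, was not simulated. Among 11106 simulated genes, the test of the read split recovered 29.0% of 200 genes changed 2-fold and 64.2% of those with 100 reads, with 3 false calls, and 66.5% of 200 genes changed 4-fold with 7 false calls. The test of the leading share, on 842 genes, recovered 90.0% of 200 genes changed by 20 percentage points with 6 false calls, and called 0 genes when none was changed. Exon inclusion, simulated at 200 spanning reads per library and averaged over both, was recovered within 10 percentage points for 500 of 500 exons. Exons near the minimum of 20 spanning reads were not simulated. The permutation test called 12 of 200 simulated sets of 940 exons with no difference. A trend over transcript length wider than the observed one was put in, so its calls do not measure length bias in these data. Observed decile medians of the log2 ratio ran from −0.23 to 0.19. With the wider trend and no gene changed, 305 of 11106 genes were called with the trend left in and 0 with it taken off. With 200 genes changed 4-fold besides, the corrected test recovered 136 with 13 false calls. The comparison with random lists called 14 of 200 lists with no shift and 200 of 200 with a shift of 0.8, and the test of exon lengths called 8 of 200 sets with no difference. The common dispersion was estimated at 0.0205, 0.0496 and 0.0993 for simulated values of 0.02, 0.05 and 0.1. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.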

Results

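The transcriptome of the left cerebral cortex was measured in 2 long-read RNA-seq libraries from male B6CASTF1/J mice at 2 months of age. Long-read sequencing reads a cDNA from end to end, so that each read shows which exons are joined in a transcript. The libraries formed 1 group of 2 replicates (n = 2), and the design had no treatment, genotype or age contrast. Replicate 1 held 1041323 assigned reads and replicate 2 held 474143 without spike-ins, a ratio of 2.20. At least 5 reads in both libraries were counted for 9792 annotated genes, and at least 1 read in both for 14076. ERCC spike-ins took 0.792% and 1.11% of the reads of replicates 1 and 2, and mitochondrial genes 0.0770% and 0.0892%. Values are given as mean ± SD over the 2 libraries unless stated.

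Abundant transcripts came from genes of protein turnover, lipid transport and neuronal membranes. Ubb, a ubiquitin precursor gene, stood at 3286 ± 271 CPM (SD, n = 2) and Hspa8, a constitutive heat shock chaperone, at 2230.2 ± 43.0 CPM. Apoe, the main lipid carrier made by astrocytes, had 3039.7 ± 712 CPM. Cpe, a carboxypeptidase that processes neuropeptides, had 3034 ± 21.9 CPM, and Ndrg4 had 2772 ± 174 CPM. Ncdn had 2478 ± 277 CPM and Snap25, a SNARE protein of synaptic vesicle fusion, 2336 ± 9.51 CPM. Calm2, a calcium sensor gene, had 2221 ± 182 CPM. Aplp1, a relative of the amyloid precursor protein, had 2185 ± 56.7 CPM, the glycolytic enzyme gene Aldoa 1974.5 ± 68.0 CPM, Sparcl1 1967 ± 49.7 CPM and the autophagy gene Gabarapl1 1961 ± 53.7 CPM. Gm15459, at 1987 ± 161 CPM, is annotated as a processed pseudogene, so its reads are uncertain. Of the mitochondrial genes, mt-Co1 had the most reads, at 216 ± 17.1 CPM.

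Marker lists of the cell types of cortex asked how much each type contributed to the reads. The 12 genes listed for neurons in general summed to 7989 ± 38.2 CPM (n = 2), led by Snap25, the neurofilament gene Nefl (1459.7 ± 27.1 CPM) and the vesicle protein gene Syp (1327 ± 11.0 CPM). Genes of glutamatergic neurons summed to 4722 ± 105 CPM, with the postsynaptic calmodulin-binding gene Nrgn at 1833 ± 149 CPM, the vesicular glutamate transporter gene Slc17a7 at 1405 ± 83.6 CPM and Arpp21 at 552 ± 73.7 CPM. Genes of GABAergic interneurons summed to 880.1 ± 120.2 CPM, with the GABA-synthesising enzyme gene Gad1 at 509 ± 18.3 CPM and the neuropeptide genes Npy at 73.5 ± 11.5 CPM and Vip at 63.8 ± 15.7 CPM. Astrocyte genes summed to 7860.1 ± 585 CPM, led by Apoe, Aldoc (1624 ± 20.6 CPM) and the glutamate transporter gene Slc1a3 (807 ± 61.1 CPM). Oligodendrocyte genes summed to 2488 ± 319 CPM, with the myelin genes Mbp at 1278 ± 50.5 CPM and Cnp at 265 ± 19.5 CPM. Their precursors' genes summed to 276 ± 38.6 CPM, led by Olig1 at 94.7 ± 8.66 CPM, Olig2 at 52.0 ± 7.93 CPM and Pdgfra at 49.8 ± 13.8 CPM. Microglial genes summed to 604 ± 43.5 CPM, with Csf1r at 139 ± 2.88 CPM and the complement gene C1qa at 54.1 ± 4.95 CPM. Endothelial genes summed to 464 ± 51.3 CPM, with the tight junction gene Cldn5 at 179.9 ± 29.0 CPM, the glucose transporter gene Slc2a1 at 81.5 ± 1.12 CPM and Itm2a at 63.8 ± 14.2 CPM. Mural cell genes summed to 196 ± 23.3 CPM, with Rgs5 at 94.7 ± 23.6 CPM, Vtn at 45.4 ± 4.42 CPM and Pdgfrb at 22.5 ± 4.91 CPM. Counted on known transcripts only, the glutamatergic sum was 2068 CPM, a change of more than 1.5 times, and the sums of all 32 lists were lower. Marker sums depend on which genes were listed and are not shares of cells.

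Genes of the cortical layers were all at low to middle levels. Upper-layer genes summed to 629 ± 70.7 CPM (400.2 on known transcripts only), with the calcium buffer gene Calb1 at 217 ± 12.9 CPM, Lamp5 at 177 ± 26.7 CPM and the transcription factor gene Cux1 at 85.0 ± 17.0 CPM. Layer 4 genes summed to 109 ± 6.52 CPM (65.0 on known transcripts only), with Whrn at 66.8 ± 1.98 CPM, Rspo1 at 28.6 ± 13.3 CPM and Rorb at 10.8 ± 6.39 CPM. Layer 5 genes summed to 124 ± 11.7 CPM (80.4 on known transcripts only), with Parm1 at 41.8 ± 11.4 CPM, and with Bcl11b at 22.0 ± 4.23 CPM and Fezf2 at 18.0 ± 1.65 CPM, both transcription factors of subcortical projection neurons. Layer 6 genes summed to 63.7 ± 11.3 CPM (33.0 on known transcripts only), with Syt6 at 17.3 ± 5.41 CPM, Ccn2 at 16.9 ± 8.94 CPM and Cplx3 at 10.5 ± 2.86 CPM. No layer gene differed between the libraries in the exact binomial test, whether adjusted over all genes tested or adjusted over the list alone.

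**Figure D1:**
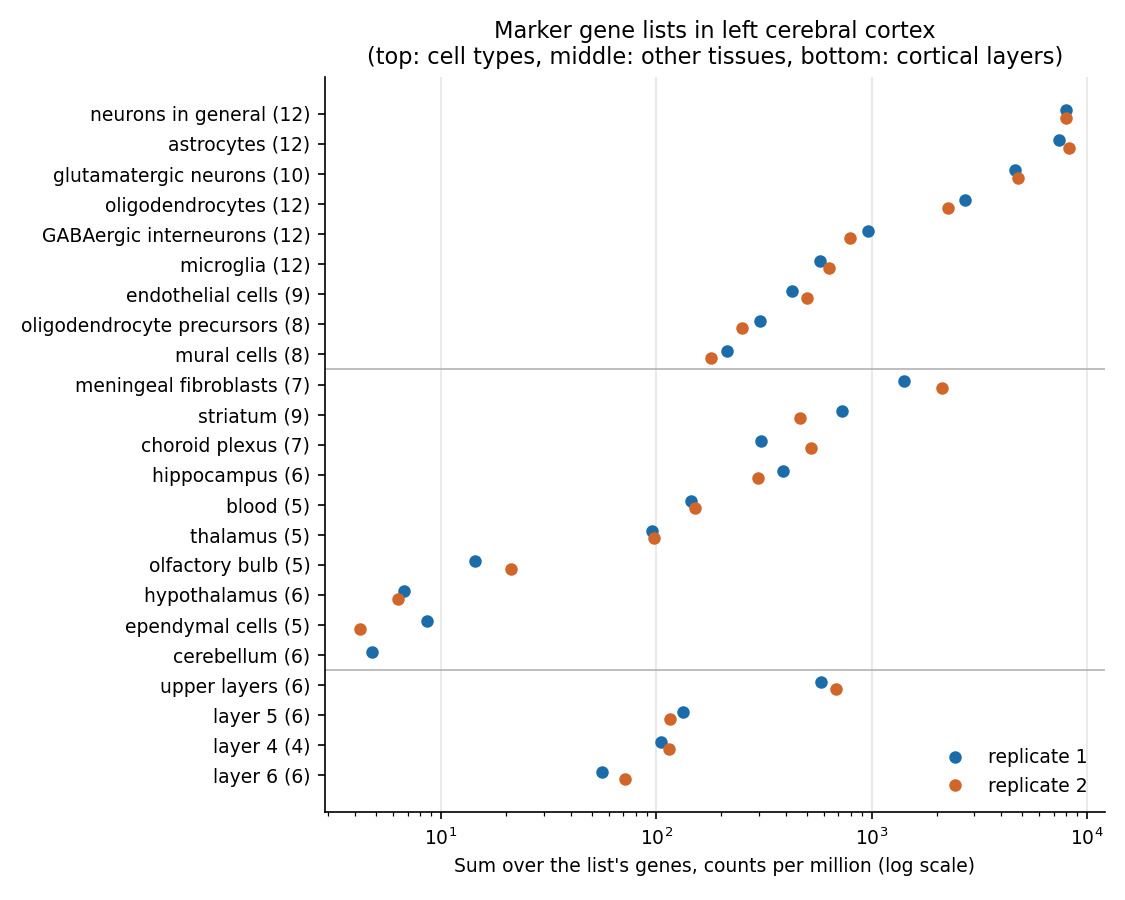
Summed CPM (log axis) of each marker list, with 1 point per library and the number of annotated genes in parentheses. Lists of cortical cell types run from 7989 CPM (mean of both libraries, neurons in general) to 196 CPM (mural cells), while the hypothalamus, ependymal and cerebellum lists lie under 10 CPM in each library, with no point for cerebellum in replicate 2, where it had no reads.

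Lists of neighbouring tissues asked what the dissection had brought along. Genes of the meninges summed to 1764 ± 496 CPM, almost wholly from Ptgds (1666 ± 504 CPM), a prostaglandin synthase that oligodendrocytes also make, while the collagen gene Col1a1 had 37.9 ± 8.87 CPM. Striatal genes summed to 595 ± 185 CPM (349.7 on known transcripts only), with Ppp1r1b, the dopamine signalling protein DARPP-32, at 229 ± 34.6 CPM. Choroid plexus genes summed to 414 ± 154 CPM, with Enpp2 at 310.1 ± 44.7 CPM and the thyroxine carrier gene Ttr at 92.9 ± 104 CPM. Kl had 8.15 CPM, Clic6 1.53, Folr1 1.05 and Aqp1 0.480 CPM on average, while Otx2 had no reads in either library. Hippocampal genes summed to 342 ± 63.4 CPM, of which Wfs1 made up 326 ± 55.2 CPM and C1ql2 8.35 ± 5.84 CPM. Lct had 5.08 CPM, Prox1 1.92 and Spink8 0.960 CPM on average, and Dsp had no reads. The choroid plexus and hippocampal sums thus rest mainly on Enpp2 and on Wfs1, and whether cortex itself made those reads was not tested. Blood genes summed to 148 ± 4.84 CPM, led by the haemoglobin genes Hba-a1 at 85.5 ± 1.39 CPM, whose split from its near-identical copy Hba-a2 is uncertain, and Hbb-bs at 33.7 ± 0.0948 CPM. Thalamic genes summed to 96.04 ± 1.38 CPM (59.3 on known transcripts only), led by Rora at 54.0 ± 7.13 CPM and Slc17a6 at 19.6 ± 0.838 CPM. Genes of the olfactory bulb summed to 17.7 ± 4.73 CPM (9.21 on known transcripts only, Cdhr1 11.8 ± 7.18 CPM, Doc2g 3.94 ± 2.58 CPM, Eomes no reads). Those of the hypothalamus summed to 6.52 ± 0.279 CPM (1.92 on known transcripts only, Pomc 3.07 ± 1.62 CPM, Avp 1.92 ± 2.72 CPM, Pmch no reads), of ependymal cells to 6.43 ± 3.13 CPM (Rarres2 3.46 ± 1.90 CPM, Dynlrb2 1.53 ± 0.812 CPM, Ccdc153 no reads) and of the cerebellum to 2.40 ± 3.40 CPM (0.480 on known transcripts only, Cbln1 1.44 ± 2.04 CPM, Pcp2 0.480 ± 0.679 CPM, Barhl2 no reads). A count of 0 allows up to 2.88 CPM in replicate 1 and 6.33 CPM in replicate 2.

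Among the functional lists, genes of synaptic vesicles and release summed to 14264 ± 448 CPM. Besides Snap25 they included Vamp2, the vesicle SNARE gene, at 1839.8 ± 159 CPM. Postsynaptic density genes summed to 3915 ± 258 CPM (2172.5 on known transcripts only), with Camk2b at 902 ± 33.4 CPM, the NMDA receptor subunit gene Grin1 at 778 ± 68.0 CPM and the AMPA receptor subunit gene Gria2 at 468 ± 32.3 CPM. GABA-A receptor genes summed to 1223 ± 134 CPM (812 on known transcripts only). Nuclear genes of oxidative phosphorylation summed to 8126 ± 531 CPM, with Cox4i1 at 1493 ± 51.1 CPM, Atp5b at 1147 ± 140.5 CPM and Atp5a1 at 914 ± 7.08 CPM. Genes listed as imprinted summed to 4302 ± 8.35 CPM, with Gnas at 1309.8 ± 0.0995 CPM and Snrpn at 1038 ± 53.0 CPM. The noncoding Meg3 had 454 ± 98.2 CPM, and H19 had no reads. Imprinting means expression from 1 parental allele, which was not examined here and need not hold for each listed gene in cortex. Long noncoding RNAs summed to 1235 ± 103 CPM, led by Meg3, Snhg11 (250.8 ± 30.1 CPM) and Miat (194 ± 11.4 CPM), and on known transcripts only to 329 CPM. Neuronal splicing regulators summed to 3607 ± 278 CPM (1643 on known transcripts only), with Celf4 at 788 ± 93.6 CPM, Rbfox3, also known as NeuN, at 635 ± 24.1 CPM and Qk at 449 ± 64.9 CPM. Immediate early genes, which neurons switch on with activity, summed to 932 ± 251 CPM, with Arc at 263 ± 120.4 CPM, Junb at 191 ± 76.6 CPM and Egr1 at 139 ± 20.7 CPM, and Fosb had 1 read in replicate 1 and 0 in replicate 2. The 67 annotated genes listed for alternative splicing in brain summed to 30270.3 ± 1579 CPM, led by Ndrg4, Snap25 and Pkm (1807 ± 85.2 CPM).

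The authors' classes of transcript models showed how the reads split between annotated transcripts and other models. Reads outside known transcripts include parts of annotated ones, so their share does not measure how much of the transcriptome is unannotated. Known transcripts took 62.8 ± 2.05% of the reads (n = 2), with 64.3% (95% Wilson interval 64.2 to 64.4%) in replicate 1 and 61.4% (61.2 to 61.5%) in replicate 2. Of the reads on known transcripts, 95.6 ± 0.353% fell on protein-coding transcripts, 1.34 ± 0.144% on retained introns and 1.00 ± 0.141% on processed pseudogenes. Incomplete splice matches took 9.79 ± 0.165%, most of them with the 5′ end missing (6.96 ± 0.108%). NIC models took 8.52 ± 0.641% and NNC models 4.93 ± 0.187%. Genomic models, which overlap a gene without following its splicing, took 5.44 ± 0.778%, antisense models 7.70 ± 1.47% and intergenic models 0.794 ± 0.0866%. Restricted to models with 5 or more reads, the known share was 76.1%.

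The share of incomplete matches followed transcript length. Their median share of a gene's reads was 3.48 ± 0.135% for genes whose leading transcript was 1977 nt or shorter and 10.8 ± 1.08% for those of 4079 nt or longer, and 4.65 ± 0.609% and 6.38 ± 0.939% in the quartiles between. Spearman's rho across 1976 genes, which are not independent replicates, was 0.346. Overlapping single-exon models could be incomplete matches in 1 library and genomic models in the other. The most-read such model of each library was compared in 226 genes where these overlapped, with at least 20 reads in each. Their class differed in 48 genes (21.2%), among them Gabarapl1 (1600 and 763 reads, 79.9% and 80.5% of the gene), Cplx2 (235 and 114 reads) and Agpat3 (228 and 116 reads), genes picked after their values were seen. Overlapping models need not be the same model. In Slc25a4 both ran from 46207136 to 46207620, while in Mbp they began at 82575601 in replicate 1 and 82584116 in replicate 2.

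On reads of known transcripts, most genes had a single leading transcript, with reads of all other models left out. Among 1284 genes with at least 50 known-transcript reads in each library, the median share of the leading transcript was 98.9% in replicate 1 and 98.5% in replicate 2. In 71.3% of these genes it exceeded 90% in each. Only 1 known transcript was seen for 442 of the 1284 genes, so their share is full by construction and raises these values. In 26 genes (2.02%, 95% Wilson interval 1.39 to 2.95%) no transcript held a majority in either library. Grin1, the obligatory subunit of NMDA receptors (chromosome 2), was the only gene of the splicing list with 100 such reads in each library whose leading transcript stayed under 60% in each. Grin1-201, with 20 exons, held 35.8 ± 0.0329% of its known-transcript reads and Grin1-205, with 19 exons, 14.1 ± 1.26% (n = 2). In 6 of the 20 splicing-list genes at that depth the leading transcript exceeded 90% in each library, as in App (App-201, 93.2 ± 0.0487%), Gnas (Gnas-208, 94.0 ± 0.136%) and Camk2b (Camk2b-209, 99.0 ± 0.565%), named after their values were seen. Known transcripts held 537 of 915 Camk2b reads in replicate 1 and 221 of 439 in replicate 2. For Gnas they held 1260 of 1364 and 577 of 621. With incomplete, NIC and NNC models counted as well, 18.4% of 1887 genes had no majority structure.

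The leading share was compared between the replicates in 842 genes with 2 or more known transcripts. Ajm1, which encodes a junction protein, was the 1 gene past the threshold, and 41 genes had an unadjusted p under 0.05. Its transcript Ajm1-203, a single exon of 2925 nt, held 26.7% of 120 known-transcript reads in replicate 1 (95% Wilson interval 19.6 to 35.2%) and 62.7% of 67 in replicate 2 (50.7 to 73.3%), with an adjusted p of 0.00181 in Fisher's exact test. Ajm1-203 led by its mean share over both libraries. In replicate 1 Ajm1-204, with 3 exons, held more, at 45.8% against 22.4% in replicate 2. The number of calls depended on how models were counted. With all structures, 23 of 1990 genes differed, among them Ajm1, Nptxr (87.6% and 73.0%) and Kif5a (77.3% and 68.1%), and with a minimum of 100 reads, which Ajm1 did not reach in replicate 2, 0 of 348 did.

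Cassette exons, which are included in some transcripts of a gene and skipped in others, were read in the genes listed for alternative splicing in brain. Snap25 exon 5 (chromosome 2, 136770057 to 136770174, coding, 118 nt) was included in 88.2 ± 2.06% of spanning reads (n = 2), and the neighbouring 118-nt exon at 136769743 to 136769860, its mutually exclusive partner, in 11.7% on average. In Pkm, the pyruvate kinase gene, the exon at 59675568 to 59675734 of chromosome 9 was included in 11.96 ± 1.01% and its 167-nt partner at 59675029 to 59675195 in 88.2% on average. In Gria2, the exon at 80690404 to 80690518 of chromosome 3, of the flip and flop pair, was included in 56.3 ± 7.92% and the other 115-nt exon, at 80691320 to 80691434, in 42.4% on average. Grin1 exon 19 (chromosome 2, 25294438 to 25294548) was included in 58.3 ± 1.40%. Ndrg4 exon 16 was included in 82.2 ± 0.668%, the 30-nt exon 13 of the calcineurin gene Ppp3ca in 79.99 ± 1.21% and the 36-nt exon 13 of Aplp2 in 86.5 ± 0.695%. Middle values were found for Dclk1 exon 13 (60.7 ± 1.21%), Bin1 exon 15 (36.9 ± 3.60%) and Ndrg2 exon 3 (33.0 ± 1.74%). Low inclusion was found for Rtn3 exon 2 (22.0 ± 0.882%), the 123-nt exon 5 of the myelin gene Mbp (18.8 ± 0.558%), Tpm3 exon 5 (14.6 ± 3.73%) and exon 22 of the calcium pump gene Atp2b2 (13.7 ± 0.0397%).

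**Figure D2:**
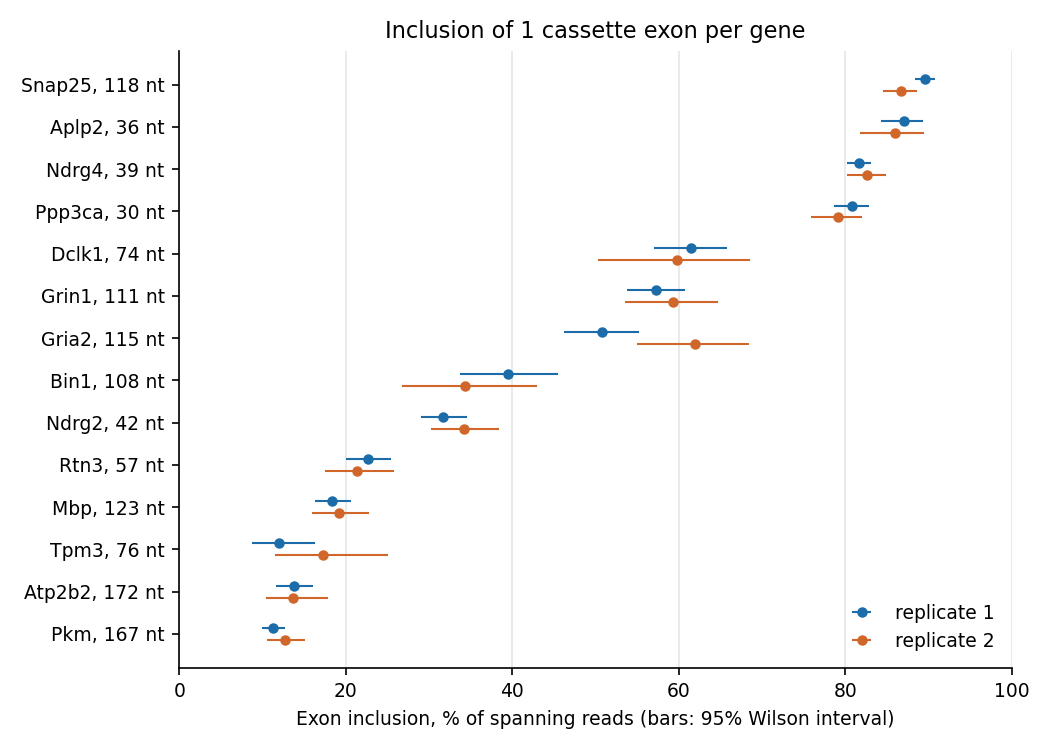
Inclusion of 1 cassette exon per gene as a percentage of spanning reads, with 1 point per library and bars for the 95% Wilson interval. The exons range from 88.2% (Snap25) to 11.96% (Pkm) on average, and the replicates lie farthest apart for Gria2, at 50.7% and 61.9%.

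Of 39371 annotated internal exons with 20 spanning reads in each library, 974 (2.47%) in 670 genes were alternative. Microexons, of 27 nt or shorter, were alternative more often than longer exons, at 43 of 328 (13.1%, 95% Wilson interval 9.88 to 17.2%) against 931 of 39043 (2.38%, 2.24 to 2.54%). The odds ratio was 6.18, with p = 5.83e-19 in a two-sided Fisher's exact test. Of the 328 microexons, 94 were included over 95% and 148 under 10% in each library, while 90.5% of the 39371 exons were near-constitutive. The aligner is not given in the sources used here, so false skipping of exons this short cannot be excluded. Alternative microexons with the most spanning reads were singled out after their values were seen. They included an 18-nt exon of the actin regulator gene Nckap1 (chromosome 2, 80571213 to 80571230) at 55.0 ± 1.70% and a 24-nt exon of Mink1 at 87.8 ± 1.29%. A 15-nt exon of the clathrin adaptor gene Snap91 stood at 83.6 ± 3.02% and a 24-nt exon of Bin1 at 86.8 ± 3.48%. Among alternative exons, the median inclusion was 70.1% for microexons and 55.0% for longer exons, a difference of 15.03 percentage points that did not pass the two-sided permutation test (p = 0.0637). Under alternatives that p ran from 0.00457 to 0.877, and 3 of them, such as a minimum of 50 spanning reads, passed the threshold. The length was a multiple of 3 in 62.6% of alternative exons of coding genes (95% Wilson interval 59.5 to 65.6%) and in 38.9% (38.4 to 39.4%) of near-constitutive ones, with an odds ratio of 2.63 and p = 1.59e-48 in a two-sided Fisher's exact test. Of the 744 alternative exons lying wholly in coding sequence, 70.4% had such a length, against 37.6% of 117 outside coding sequence and 35.4% of 113 partly in it. On known transcripts only, 318 exons were alternative.

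Splice chains absent from the annotation were matched between the libraries. With at least 2 reads in each library, 4412 such chains of 2598 genes were found, 3365 of them NIC and 1047 NNC by their class in replicate 1, while 398 (9.02%) had another class in replicate 2. Of the chains in genes with 20 reads in each library, 62 held a majority of the gene's reads in each. The chain with the most reads belonged to Nrgn (chromosome 9, 37538319 to 37552904), where a chain of 3 exons with 1 unannotated intron, at 37545349 to 37545947, took 93.6 ± 0.175% of the gene's reads, 1681 in replicate 1 and 861 in replicate 2. Oaz1 encodes the antizyme of polyamine synthesis, and its mRNA is read with a frameshift. A chain of its annotated introns took 94.0 ± 1.55% of the gene's reads, and in its relative Oaz2 such a chain took 88.7 ± 1.23%. Whether these chains differ from annotated ones in more than how the frameshift is annotated was not examined. Chains of Pitpna (90.9 ± 2.86%) and Trim44 (82.8 ± 2.84%) used an unannotated intron, at 75603485 to 75609104 of chromosome 11 and 102304505 to 102357400 of chromosome 2. The septin gene Sept7 had an unannotated chain at 82.0 ± 1.76%, the adaptor gene Apbb1 at 62.1 ± 3.73%, the corepressor gene Ctbp1 at 59.3 ± 2.78%, Flywch1 at 45.6 ± 6.29% and the vesicle GTPase gene Rab3a at 26.9 ± 0.878%. With a minimum of 1 read the number of shared chains was 12125, and with 5 reads 1336.

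The replicates were compared gene by gene to see where these 2 libraries differed by more than read sampling, which says nothing of conditions. Higher in replicate 1 were Rhbdl1 by 1.31 on the log2 scale, the neurite guidance gene Farp1 by 1.24, Penk, the enkephalin precursor of striatal neurons, by 1.13, the protein kinase A inhibitor gene Pkia by 1.10 and Dcaf7 by 0.97. Lower in replicate 1 were the clathrin light chain gene Clta (log2 ratio −1.08), the ribosomal gene Rpl13a (−1.07), Id2 (−1.04), Bscl2 (−1.04) and Arc (−1.01). Their adjusted p ran from 1.49e-07 for Arc to 0.0311 for Penk and Dcaf7 in the exact binomial test, and none of these 10 genes was called by the negative binomial test. Of 10 immediate early genes tested, Arc and Junb (−0.88) were lower, and 4 were lower when adjusted over the list alone. Among other listed genes, Ttr, the only listed gene that the negative binomial test also called, was lower by the widest margin (−3.15, 19.2 and 167 CPM), and the choroid plexus list had 1 lower gene, or 2 when adjusted over the list alone. Apoe (−0.52) was the 1 astrocyte gene lower of 12, with 2 adjusted over the list alone, and Ptgds (−0.66) the 1 meningeal gene by either adjustment. Of 19 oxidative phosphorylation genes, Cox5a (−0.76), Cox8a (−0.42) and Atp5b (−0.29) were lower by either adjustment. Of 10 oligodendrocyte genes 1 was higher by either adjustment, and Penk was the 1 higher striatal gene of 8, with 3 adjusted over the list alone. Of 66 splicing-list genes 3 were higher, among them Dclk1 (0.70) and Atp2b2 (0.32), and Clta was lower, against 7 higher and 1 lower adjusted over the list alone. Of 15 synaptic vesicle genes, Stx1a (−0.40) was lower, against 4 higher and 2 lower adjusted over the list alone, and Meg3 (−0.48) was lower in the imprinted and the noncoding list by either adjustment. Adjusted over the list alone, 1 glutamatergic gene was higher and 1 lower, 1 GABAergic gene higher and 1 gene of neurons in general lower, none of which passed over all genes, and the remaining lists had 0 by either adjustment.

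Over all genes, 103 of 11106 differed in the exact binomial test, 48 higher and 55 lower in replicate 1, and 29 of them by 2-fold or more, while 1106 had an unadjusted p under 0.05. Without a minimum of reads the numbers were 52 higher of 87. The common dispersion gave a coefficient of variation of 10.6% between the replicates, and 96.1% of 2015 genes with 50 reads in each library lay within 1.5-fold. Pearson's r of log2 CPM across genes with 5 reads in both was 0.947 and Spearman's rho 0.938, across genes that are not independent replicates. An edgeR negative binomial exact test with that dispersion, which was estimated from the same 2 libraries, called 7 genes, all among the 103 (Ttr, Wdr92, Pcdhga2, Gm49450, Gm21986, Gm11223 and Gm6969, of which the protocadherin and the pseudogenes share sequence with other genes and are uncertain). The ratio followed transcript length, from a median log2 ratio of −0.17 in the decile of shortest transcripts to 0.19 in that of the longest, and with that trend taken off 56 genes differed, 41 of them among the 103. Set against random lists matched on expression, a comparison chosen after seeing the data, 8 of 27 lists had a median outside the central 95%, where 1.35 were due by chance.

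**Figure D3:**
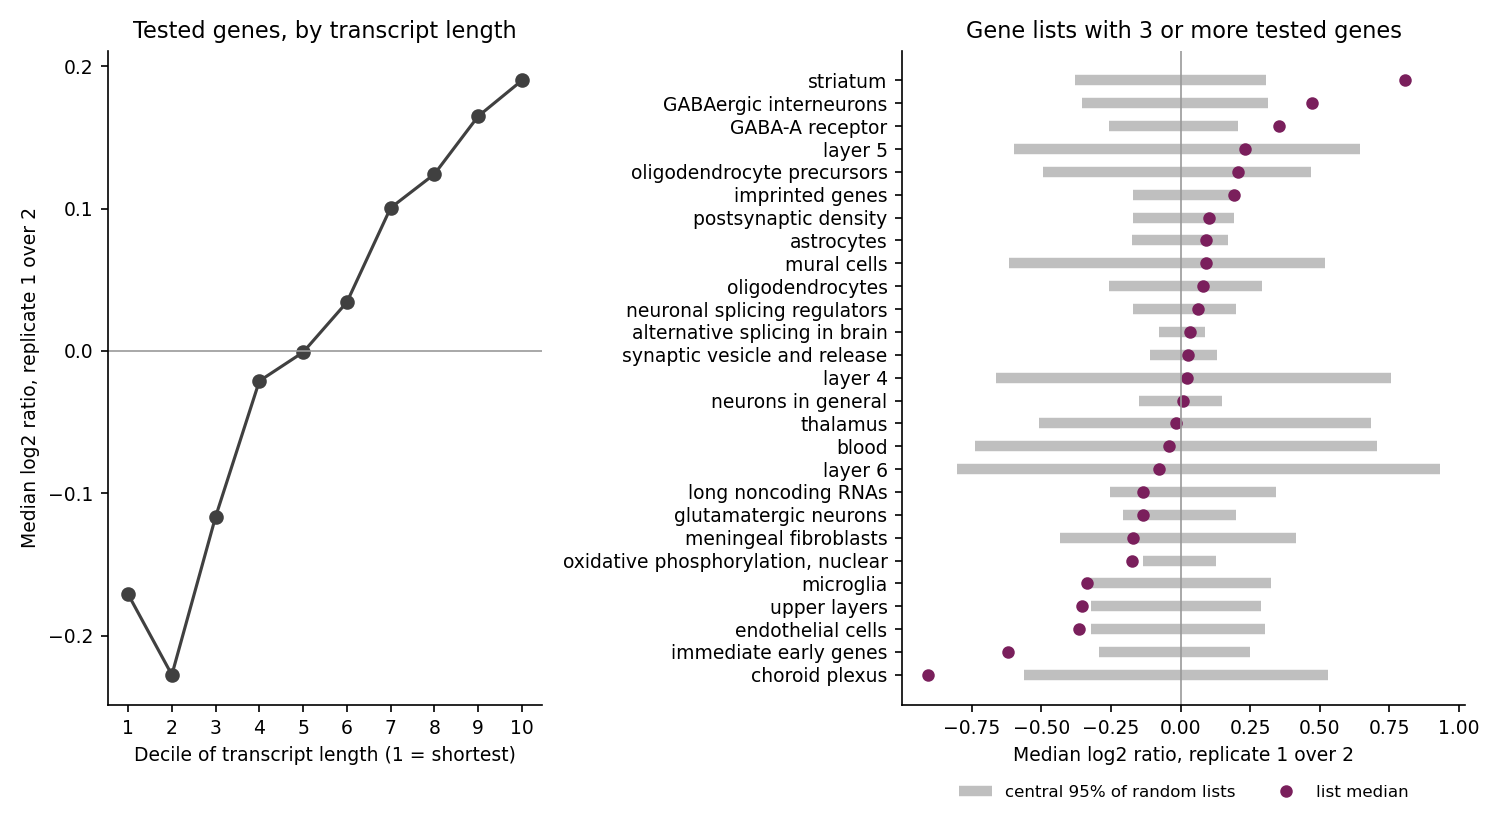
Left, median log2 ratio of replicate 1 over replicate 2 for tested genes by decile of transcript length, at −0.17 in the first decile, −0.23 in the second and 0.19 in the last. Right, median log2 ratio of each gene list (points) with the central 95% of 10000 random lists of the same size matched on mean expression (bars), where striatal genes lie farthest above at 0.81 (8 genes) and choroid plexus genes farthest below at −0.91 (3 genes).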

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

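Both tests in this part were chosen before their results were seen. Reads on models antisense to annotated genes were looked at because no comparison used them and their number lay far above what a count of 0 allows. Counted over all models of such genes, they came to 71466 in replicate 1 and 43313 in replicate 2, of which 69347 and 41460 were in the antisense class of transcript models. A single model opposite Gm26917, at 39843013 to 39848035 of chromosome 17 on the minus strand, held 15390 and 7984 of them, or 1.48% and 1.68% of all reads. Gm26917 is annotated at the repeat of the 45S ribosomal RNA precursor, and the gene itself had 20 and 11 reads. The other models with many reads lay opposite Snhg11 (1615 and 1068 reads), Cplx2 (1307 and 821), Slc1a2 (1326 and 743) and Shank1 (1234 and 749). The genes themselves had fewer reads, with Snhg11 at 239 and 129, Cplx2 at 270 and 123, Slc1a2 at 320 and 120 and Shank1 at 49 and 23. In each library, 97.8% of the reads of the antisense class had a single exon.

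Sense reads given the wrong strand at an equal rate would make antisense reads follow the level of the gene opposite. Spearman's rho between them, averaged over the libraries, was 0.0714 across 2015 genes, which argues against such an equal rate in these genes. Gm26917 (20 and 11 reads) and Shank1 (49 and 23) had too few reads to be among them. The level counted all reads of a gene, while 97.8% of antisense-class reads had a single exon. A wrong strand for single-exon sense reads alone was therefore not tested. Priming on A-rich stretches of the antisense strand could place 3′ ends next to such stretches. Where sequence was at hand, the T share of the sense strand next to these ends was 9.44 percentage points above random positions. That is the mean of the median differences in replicate 1 (8.38) and replicate 2 (10.5). Only 29.4% and 33.2% of the models had such sequence, so the test was void. Priming, or a wrong strand for single-exon sense reads, cannot be told apart as a source from transcription of the opposite strand. With a single group, no biological explanation was tested.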

How the results depend on the processing

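The length correction and the run without striatal genes were chosen after the result was seen, and all other alternatives before. In the alternatives that matched all structures, the pooling of single-exon models was also chosen after seeing the data. Apart from marker lists, 34 of 51 values under alternatives stayed on the same side of their threshold or within the stated margin, leaving aside the known share with 1 replicate left out. That margin was 1 SD for shares and 1.5 times for counts, for the dispersion (0.0111) and for rho, where no spread was at hand. Lengths that are a multiple of 3, the dispersion, the number of detected genes and the relation of incomplete matches to length kept their direction or size under each alternative run for them. The known share was 76.1% with models of at least 5 reads, since that minimum takes out the many unannotated models with 1 read. Genes that differ between the libraries numbered 7 (1 higher) under the negative binomial test, which adds spread beyond sampling, and 56 with the length trend taken off. Leading shares differed in 0 genes at a minimum of 100 reads, where 348 were tested and Ajm1 had too few reads, and in 23 with all structures, Ajm1 among them. Genes without a majority transcript made up 0.765% at a minimum of 100 reads and 18.4% with all classes. Shared unannotated chains numbered 12125 at 1 read and 1336 at 5. Alternative exons numbered 1556 at 10 spanning reads, 340.0 at 50, 318 on known transcripts and 1196 to 2170.0 with 1 replicate left out, the highest without replicate 2. The difference between microexons and longer exons was −3.07 percentage points for exons of 15 nt or shorter (p = 0.877, 4 microexons), 12.7 at 10 spanning reads (p = 0.0399), 30.4 at 50 (p = 0.00457) and 25.2 on known transcripts (p = 0.0333), by permutation. The cause of these changes was not tested, beyond what the alternative itself sets.

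Leaving out 1 of 2 replicates moves a mean by less than 1 SD by construction, so those 64 marker list values test nothing. Of the other 96, 70 stayed within 1 SD of the main value, and 26 moved, all on known transcripts only, where reads of unannotated models leave the sum but not the total. In CPM these were glutamatergic neurons 2068, GABAergic interneurons 632, neurons in general 6038, astrocytes 5899, oligodendrocytes 2109, their precursors 208, microglia 522, endothelial cells 368, mural cells 162, striatum 349.7, hippocampus 269, thalamus 59.3, hypothalamus 1.92, olfactory bulb 9.21, upper layers 400.2, layer 4 65.0, layer 5 80.4, layer 6 33.0, synaptic vesicle 11481, postsynaptic density 2172.5, GABA-A receptor 812, imprinted 3165, splicing regulators 1643, oxidative phosphorylation 6922, noncoding RNAs 329 and splicing in brain 20622.

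Depth limited the smaller library. Thinned to the depth of replicate 2, replicate 1 had 9910.0 genes with 5 reads against 9925 in replicate 2, and 9125 genes were then detected in both. No paired analysis was possible because the series has 1 group.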

Other observations

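The test of striatal genes against random lists, the test of length as the whole cause and the look at all lists were chosen only after the result was seen, and genes in the next paragraph were named after their values were seen.

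The 26 genes without a majority transcript included the glycoprotein gene Gpm6b, whose leading transcript held 24.6% of known-transcript reads on average, the kinase genes Csnk1a1 (33.9%), Mapk9 (44.1%) and Camk2d (45.2%), and the transcription factor genes Tcf4 (39.3%) and Mef2c (40.1%). In Gria1, the 115-nt exons at 57309769 to 57309883 and 57310608 to 57310722 of chromosome 11 were included in 67.7% and 32.0% of spanning reads on average. Among genes that differed between the libraries, the kinesin motor genes Kif5a (log2 ratio 0.47) and Kif5c (0.33) were higher in replicate 1, while the ferritin genes Fth1 (−0.39) and Ftl1 (−0.71), which have near-identical pseudogenes, and the creatine kinase gene Ckb (−0.61) were lower. Counted over all models of such loci, intergenic loci numbered 3801 and 2484 with 7956 and 4116 reads, of which 7632 and 4056 were in the intergenic class of transcript models. Of those shared by both libraries, the spliced one with the most reads, with 2 exons on the plus strand of chromosome 4 (133095893 to 133101553 in replicate 1), had 349 and 90 reads.

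The 8 tested striatal genes were all higher in replicate 1 by value, with a median log2 ratio of 0.81, of which Penk passed the test over all genes. Read sampling would leave that median inside the range of random lists, and it lay at percentile 99.98 of 10000. A median of 0.84 with the length trend taken off argues against transcript length as the source. More striatal tissue in replicate 1 is a candidate explanation, because a second list of striatal genes that shares none with the first had a median of 0.56, at percentile 99.99, with 9 of 11 genes higher by value, the most abundant being Pde1b (197 and 165 CPM) and Gng7 (188 and 124 CPM). Cortex also expresses some of these genes, 8 of the 9 first-list genes had reads in both libraries, and genes of GABAergic interneurons had a median of 0.47, at percentile 99.7. With a single group, no biological explanation was tested.

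The 103 genes that differ may in part reflect transcript length, as rho between length and the log2 ratio was 0.264 across 10525 genes and taking off the trend left 56 genes. Length as the whole cause was not borne out, since 41 of the 103 were still called. Taking off the trend over GC content left 99 genes, 87 of them among the 103, which argues against it as the source of most calls. With a single group, no biological explanation was tested.

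Immediate early genes had a median log2 ratio of −0.62 over 10 tested genes, outside the range of random lists. The choroid plexus median of −0.91 also lay outside it but rests on 3 tested genes and is the ratio of Kl, with 6 and 5 reads, while Enpp2 stood at −0.33. Medians of the GABA-A receptor (0.35), endothelial (−0.37), upper-layer (−0.35) and oxidative phosphorylation (−0.17) lists also lay outside it. The last 2 fell inside once the length trend was taken off (−0.25 and −0.08). The GABA-A receptor median then went to 0.22 (percentile 98.55) and the endothelial median to −0.38 (percentile 1.06), both still outside. The imprinted list moved out (percentile 97.2 before and 99.4 after), and the GABAergic median went from 0.47 to 0.70.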
